A study of Lactiplantibacillus plantarum with 16 samples.

How the data were processed

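Total RNA of 8 cultures of Lactiplantibacillus plantarum WCFS1 was measured on 16 two-colour oligonucleotide arrays. The cultures were 4 grown with citrate (named 1 to 4) and 4 grown with heme, K2 and nitrate (named A to D). Each array carried the RNA of 1 culture in Cy3 (channel 1) and of another in Cy5 (channel 2), with no common reference. Each culture was on 4 arrays, 2 in each dye. Of the 16 arrays, 10 set a nitrate culture against a citrate culture, 5 in each dye orientation, and 6 set 2 cultures of the same condition against each other. The series' design text gives the cultures as the biological replicates and as grown independently, which was not tested here, so the culture and not the array was taken as the replicate (n = 4 against 4).

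Each array's deposited file is the output of image quantification with 15744 spots, and its columns, per the file headers, are the mean signal intensity of each spot and its local background intensity in both channels, not background-subtracted and not normalized. The software is not given in the sources used here. The files name the channels 1 and 2 without a dye, and the dyes were taken from the labels of the 2 channels, on which the direction of every fold change rests. The deposited series value table holds, as a comparison with the intensities showed, the authors' log2 ratio of channel 1 over channel 2 (Cy3 over Cy5) for each spot. On each array it correlated with the log2 Cy5 over Cy3 intensity ratio at r = -0.998 to -0.911 over spots. The medians of its 16 columns lay between -0.0149 and 0.0423, so the values are centred near 0, while the exact scaling stays unknown. Its 18773 missing values are the 18773 spots whose signal did not exceed the mean local background in at least 1 channel. The submitters' processing notes name limma without a version.

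The 16 arrays hold 9170 probes for 3092 loci with an lp locus tag, besides 536 control spots and 70 spots of probes without a locus tag. The background was corrected with normexp (offset 50) on the mean signal and the median local background, and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots and rejected spots at weight 0. Spots that the image software had given flag 1 or 3 (1.60% to 20.5% of the organism's spots per array) were left out. The files hold no call for spots well above background. In its place, the software's mark for an empty spot was used, and a probe was kept where at least 50% of the channels of 1 condition were not empty. The mark is no fixed measure of signal over background. On the array of cultures B and 4, 64.2% of Cy5 spots were marked empty, at a median signal of 1485 against a background of 611. The marked share also differed between arrays of like median Cy3 signal, at 30.3% (2 with B, signal 1815) and 62.4% (A with 2, signal 1771). This kept 5937 probes. Spots of a probe were averaged. For each probe, the 16 log2 ratios were solved by least squares for 8 culture levels, centred on their mean, and 1 dye term, and the probes of a locus were averaged. Of the 471 changed loci described in the report, 386 had over 1 probe, and in all 386 the probes changed in 1 direction.

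The 4 nitrate and 4 citrate levels of each locus were compared with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3, two-sided), with Benjamini-Hochberg adjustment over the 2459 loci tested and a threshold of 0.05. A run was counted where at least 4 consecutive measured loci, in order of locus number, passed the threshold in 1 direction, and the number of loci in runs was set against 1000 seeded shuffles of the order. These tests, the run rule and the rule for single loci were chosen before the data were examined. That rule takes the 15 loci with the largest change in each direction among those that passed the threshold with all 4 nitrate cultures on one side of the 4 citrate cultures. The files do not pair locus tags with gene names, and the gene table supplied is of another strain: 0 of the 3092 locus tags matched it. Gene names are therefore not given, the gene lists and the list-based naming rules prepared beforehand were not applied, and only the first 2 loci in each direction are printed. In place of the lists, windows of 100 locus numbers were tested with limma's camera with a preset correlation of 0.01 and with an estimated one. The windows and the classes of locus tags were chosen after the format of the tags was seen.

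Where a locus was marked empty in every channel of 1 condition, an approximate bound of its fold change is given. It comes from channel levels after normexp, loess and Aquantile normalization. The dim condition was set to the lowest level of non-empty spots or its own level, whichever was higher. The slide of each array was read from the spot coordinates: the arrays form 2 sets of 8, each covering the 8 positions of a slide once. Both slides hold all 8 cultures and so both conditions, and slide was tried as a block and each slide on its own.

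From the probe log2 ratios onward, the procedure was tested on simulated data with 2459 loci and 200 changed loci in the comparison of nitrate with citrate. It recovered 12 of 57 loci with a log2 change of 0.5 (21.1%), 48 of 57 with a change of 1 (84.2%) and 84 of 86 with a change of 2 (97.7%), and it called 5 of 2259 unchanged loci. It found 4 of 5 planted runs of 6 loci and no other run. The simulated noise was drawn independently for each locus and culture, with SDs of the fitted levels and of the array residuals. The SDs of the fitted levels already hold some array noise. Background correction, loess, the empty-spot filter and correlation between loci or cultures were not simulated. False calls and false runs under correlated noise were therefore not tested. The numbers of cultures and of arrays limit the precision.

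Alternatives covered the background correction, the normalization within and between arrays, separate channels, the filter on dim probes, the summary of probes, the dye term, the slide, the set of arrays, models over arrays in place of cultures, variance moderation, a 2-fold threshold, the authors' log2 ratios and the omission of each culture in turn. Keeping the rejected spots, a dye term for each column of the slides, a block for 2 sets of cultures and the omission of 1 culture per condition were added after the data were seen.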

Results

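Transcript levels were measured in Lactiplantibacillus plantarum WCFS1, a lactic acid bacterium, grown anaerobically in pH-controlled batch cultures in CDM with mannitol. The comparison asks which transcripts differ between cells given heme, K2 and nitrate and cells given citrate. Of the 8 cultures, 4 had received citrate and 4 heme, K2 and nitrate, and they are called citrate and nitrate cultures for short. The effects of citrate, heme, K2 and nitrate cannot be told apart in this design. Reduction of nitrate or citrate was not measured here. Their RNA was hybridised in pairs on 16 two-colour arrays on 2 slides. The median spot signal was 1368 to 2116 in Cy3 and 1168 to 1660 in Cy5, against a median local background of 557 to 654. Between 28.4% and 64.2% of the organism's spots in a channel were marked empty by the image software. Levels are log2 values relative to the mean of the 8 cultures, and fold changes are nitrate minus citrate on the log2 scale. The files pair no gene names with the locus tags, so regions are given by locus number, the digits of the tag.

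Transcripts of 290 of the 2459 measured loci were higher and those of 181 were lower in the nitrate cultures (limma, adjusted p under 0.05), which is 19.2% of the loci. Of these, 160 were higher and 73 lower by at least 2-fold. The 4 nitrate cultures lay entirely on one side of the 4 citrate cultures for 551 loci (22.4%), where chance gives 2.86%, and 430 of the changed loci were among them. The median log2 fold change of all loci was -0.02, and the median standard error of a log2 fold change was 0.18. With a dye term for each slide the counts were 291 and 180. The 8 arrays of the first slide alone gave 270 higher and 171 lower loci, and those of the second slide 251 and 150. Fits that take the arrays rather than the cultures as replicates gave more calls, with 568 higher and 488 lower loci where all 16 arrays counted as independent. A block for 2 sets of cultures, found in the same levels, gave 354 and 273.

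**Figure D1:**
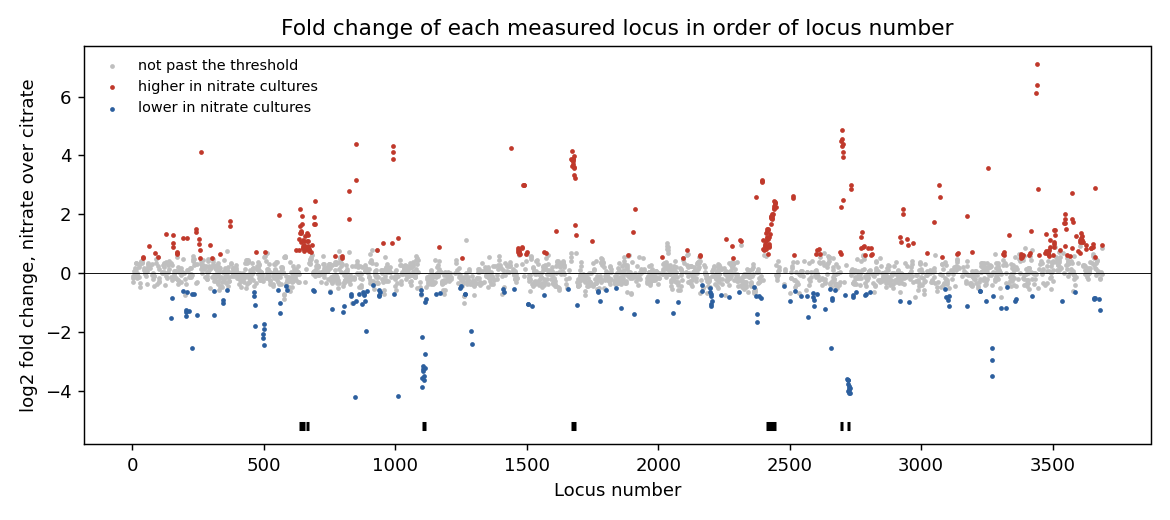
Log2 fold change (nitrate over citrate, vertical axis) of each measured locus in order of its locus number (horizontal axis), with 1 point per locus, red for loci higher and blue for loci lower in the nitrate cultures at an adjusted p under 0.05 and grey for the rest. Black bars under the points mark the 7 runs of 10 or more changed neighbours, and the highest points, at 7.10 and 6.39, are lp_3442 and lp_3441.

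The largest single increases were at lp_3442 and lp_3441. lp_3442 was 7.10 higher in the nitrate cultures (standard error 0.21, limma adjusted p = 5.77e-09), with relative levels of 3.55 ± 0.37 in the nitrate and -3.55 ± 0.27 in the citrate cultures (SD, n = 4 each). lp_3441 was 6.39 higher (standard error 0.17, limma adjusted p = 5.77e-09). In the citrate cultures these loci had a non-empty spot in only 5 and 6 of 16 channels, against 15 of 16 for each in the nitrate cultures. Their citrate levels may therefore lie close to the background. The largest decreases were at lp_0848, with a log2 fold change of -4.20 (standard error 0.35, limma adjusted p = 1.16e-05), and at lp_1012, with -4.19 (standard error 0.21, limma adjusted p = 4.03e-07), or -3.57 without nitrate culture B. Without background correction the log2 fold changes of lp_3442, lp_3441, lp_0848 and lp_1012 were 5.59, 4.78, -3.40 and -3.63. lp_1012 had at least 1 non-empty spot in all 16 channels of both conditions, and lp_0848 in 16 of the citrate and 15 of the nitrate channels. The mean share of non-empty spots was lower in nitrate than in citrate cultures, at 0.60 against 0.82 (lp_1012) and 0.42 against 0.75 (lp_0848). Part of their nitrate signal may thus have lain close to the background, which could set the size of these decreases. The relative level of lp_0848 was 2.10 ± 0.74 in the citrate and -2.10 ± 0.43 in the nitrate cultures (SD, n = 4 each). The 15 largest increases ranged from 4.12 to 7.10 and the 15 largest decreases from -4.20 to -3.61. Of these, 10 and 13 loci lay in the runs described next. A single locus was marked empty in every citrate channel, and its log2 fold change was 4.23 (limma adjusted p = 6.09e-07). With its citrate level set as for the bound described above, its transcript was 13.8-fold higher in the nitrate cultures. This value rests on the background correction and on the lowest non-empty spots, so it is not a strict lower limit.

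Changed loci lay together. There were 24 runs of 4 or more neighbouring measured loci that changed in 1 direction, 15 higher with 136 loci and 9 lower with 56 loci. Together these 192 loci were 41.3% of the changed loci with a locus number. In 1000 shuffles of the order the median was 0 and the highest 16 loci in such runs (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). With a dye term for each slide 184 loci lay in runs, and on the first and second slide alone 186 and 167.

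The longest run covered 32 measured loci between locus numbers 2410 and 2447, all higher in the nitrate cultures, with a median log2 fold change of 1.74 and a range of 0.63 to 2.44. Its mean level was 0.84 ± 0.15 in the nitrate and -0.84 ± 0.25 in the citrate cultures (SD, n = 4 each). The adjoining run from 2404 to 2408 held 5 more higher loci, with a median of 0.91. A second region of increases had 18 higher loci from 635 to 656, with a median of 1.21, and 11 from 661 to 672, with a median of 0.90. The nitrate cultures lay at 0.64 ± 0.10 and the citrate cultures at -0.64 ± 0.13 (SD, n = 4 each) in the run from 635 to 656.

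Larger increases occurred in 2 other runs. The 11 loci from 2693 to 2704 were higher by a median of 4.12, about 17.4-fold, or 7.67-fold without background correction, and their mean level was 1.67 ± 1.09 in the nitrate and -1.67 ± 0.15 in the citrate cultures (SD, n = 4 each). Culture D, at 3.29, stood above the other nitrate cultures, at 0.93 to 1.31, and without it the median was 3.48. The 15 loci from 1670 to 1686 were higher by a median of 3.70, about 13.0-fold, or 9.43-fold without background correction. Their nitrate level was 1.71 ± 0.42, but the citrate level, -1.71 ± 2.12 (SD, n = 4 each), varied widely. Citrate culture 1 lay at 1.06, below the nitrate cultures at 1.25 to 2.16. Citrate culture 3 lay at -1.18, and cultures 2 and 4 lay lower, at -3.28 and -3.46. The median was 4.61 without culture 1 and 3.08 without culture 4.

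There were 2 long runs of decreases. The 11 loci from 2719 to 2729 were lower by a median of -3.89 on the log2 scale, with a range of -4.08 to -3.61, and followed in the numbering the run of increases that ended at 2704. These loci had a non-empty spot in 3 to 16 of the 16 nitrate channels (median 12) against 14 to 16 of the citrate channels. For some of them the nitrate signal may have lain close to the background, which could set both the size and the range of these decreases. Their mean level was 1.93 ± 0.92 in the citrate and -1.93 ± 0.22 in the nitrate cultures (SD, n = 4 each), with citrate culture 1 lowest of its condition at 0.69. The 12 loci from 1101 to 1115 had a median log2 fold change of -3.24, about 9.48-fold lower (7.31-fold without background correction). Their mean level varied little between cultures of a condition, at 1.43 ± 0.11 with citrate and -1.43 ± 0.23 with nitrate (SD, n = 4 each). Single loci could vary more. At 1 of them the citrate cultures lay at 1.32 to 2.71 and the nitrate cultures at -2.79 to -0.99.

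**Figure D2:**
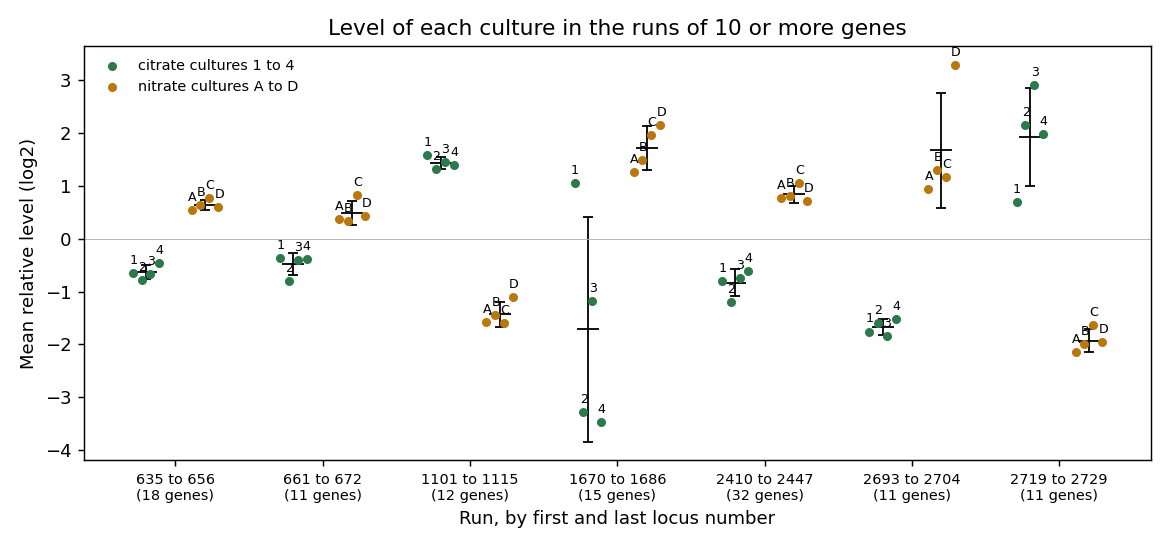
Mean relative log2 level (vertical axis) of the loci in each of the 7 runs of 10 or more changed neighbours (horizontal axis, by first and last locus number), with 1 point per culture, green for citrate cultures 1 to 4 and orange for nitrate cultures A to D. Horizontal marks and bars give the mean and SD of 4 cultures; citrate culture 1 lies at 1.06 in the run from 1670 to 1686 and nitrate culture D at 3.29 in the run from 2693 to 2704.

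Among the shorter runs, the largest increases were in the 4 loci from 989 to 992, with a median log2 fold change of 4.00, and in the 5 loci from 1482 to 1489, with a median of 2.98. Some of these loci were often marked empty in the citrate cultures, with a non-empty spot in 1 to 15 and in 4 to 16 of 16 citrate channels. Without background correction the medians were 3.10 and 1.81. Nitrate cultures lay at 1.67 ± 0.27 and citrate cultures at -1.67 ± 0.06 (SD, n = 4 each) in the run from 989 to 992. The 4 loci from 691 to 694 were higher by a median of 1.79, the 6 from 3545 to 3551 by 1.70, and the 8 from 3605 to 3614 by 1.12. Decreases of several-fold were found in the 4 loci from 3269 to 3272, with a median of -2.76, and in the 5 loci from 497 to 501, with a median of -2.08. Without background correction these 5 medians were 1.48, 1.15, 1.02, -2.46 and -1.66.

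Within each slide the medians of the long runs kept their direction. Both slides carry RNA of the same 8 cultures, and the runs were chosen in the fit to all 16 arrays. The slides therefore repeat the measurement and are not independent support for the runs. On the first slide, only the arrays of culture 4 with D and of culture A with 1 carried both conditions. The medians on the first and second slide were 1.61 and 1.79 for the run from 2410 to 2447, and 1.16 and 1.22 for that from 635 to 656. For the run from 661 to 672 they were 0.90 and 0.95, for that from 2693 to 2704 they were 3.82 and 4.14, and for that from 1670 to 1686 they were 3.78 and 3.56. For the decreases they were -3.72 and -3.92 in the run from 2719 to 2729, and -3.22 and -3.20 in that from 1101 to 1115. With a dye term for each slide the medians were 1.74, 1.21, 0.90, 4.12, 3.60, -3.89 and -3.22 in the same order, and without background correction they were smaller in size, at 1.21, 0.73, 0.58, 2.94, 3.24, -2.73 and -2.87. The long runs of increases also held loci often marked empty, with at least 1 non-empty spot in a median of 12 to 15 of 16 citrate channels. The median share of non-empty citrate spots was 46.5% (2410 to 2447), 35.9% (635 to 656), 40% (661 to 672), 45.2% (2693 to 2704) and 71.3% (1670 to 1686). In the nitrate cultures these shares were 64.8% to 93.3%. Over all the organism's spots, citrate channels were also marked empty more often on average than nitrate channels, so part of this gap may be general. A locus that did not pass the threshold, with a log2 fold change of -0.08, had non-empty shares of 0.47 with citrate and 0.93 with nitrate. Another, with a log2 fold change of 0.21, had 0.73 in both.

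Summarised in 37 windows of 100 locus numbers, increases were most frequent in 2 windows. In locus numbers 2401 to 2500, 37 of 53 measured loci were higher and 1 lower. In 601 to 700, 37 of 84 were higher and 2 lower. Toward the end of the numbering, 18 of 65 loci were higher in 3401 to 3500, 22 of 65 in 3501 to 3600 and 18 of 61 in 3601 to 3700, against 1, 2 and 5 lower. Decreases were most frequent in 2701 to 2800, with 17 of 75 loci lower and 13 higher, in 801 to 900, with 15 of 71 lower and 4 higher, and in 1101 to 1200, with 14 of 71 lower and 1 higher. By limma's camera with a preset correlation, 8 windows passed the threshold, 6 upward and 2 downward, but none did with a correlation estimated from the cultures. With the preset correlation the smallest adjusted p values were 6.78e-17 for 2401 to 2500, 6.25e-08 for 601 to 700 and 1.89e-06 for 3501 to 3600, all upward, and 2.63e-06 for 1101 to 1200, downward. With the estimated one they were 0.40 for 3501 to 3600 and 0.20 for each of the other 3 windows. With a dye term for each slide 8 windows passed under the preset correlation, and on the first and second slide alone 9 and 8.

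**Figure D3:**
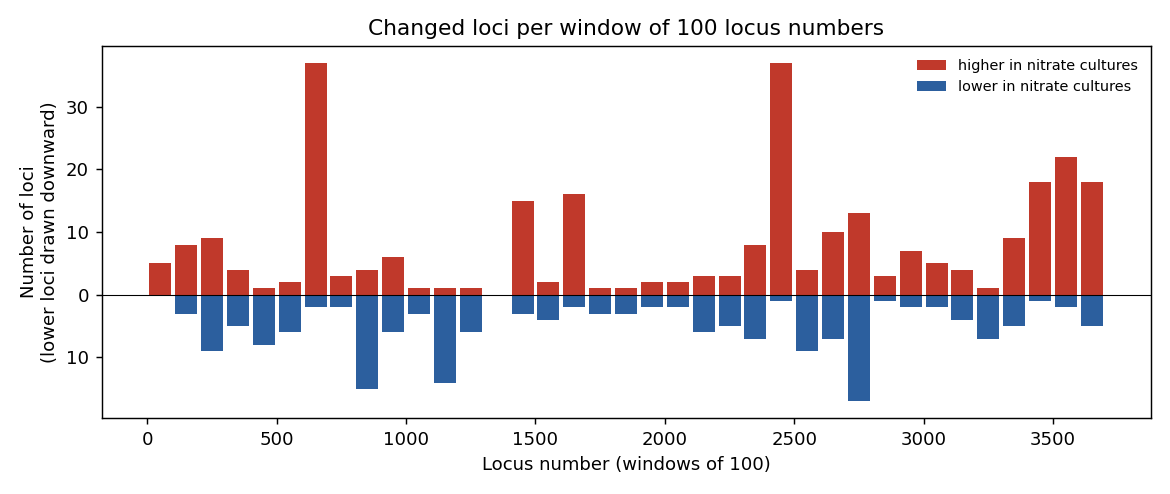
Number of loci higher (red, upward) and lower (blue, downward) in the nitrate cultures at an adjusted p under 0.05 (vertical axis) in each window of 100 locus numbers (horizontal axis). The 2 tallest bars, with 37 higher loci each, are the windows 601 to 700 and 2401 to 2500.

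Loci whose tags carry p1, p2 or p3 in place of a plain number mostly did not pass the threshold, and neither did most numbered loci (1949 of 2414). Of 36 measured p3 loci 4 were higher and 0 lower, with a median log2 fold change of -0.15 and a range of -0.54 to 1.34. Of 2 measured p2 loci 1 was lower, and the single measured p1 locus did not pass the threshold. None of the 4 measured loci with tRNA in the tag passed the threshold, with log2 fold changes of -0.25 to -0.12.

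The arrays that set 2 cultures of 1 condition against each other show the spread between cultures together with array and dye noise. The SD of log2 ratios over probes was 0.47 to 0.66 on these 6 arrays and 0.86 to 1.08 on the 10 arrays with both conditions, so the 2 ranges did not overlap. All 6 arrays with 1 condition were on the first slide, and most with both conditions on the second. On the first slide, the arrays of culture 4 with D and of culture A with 1 gave 1.01 and 0.99. On the 5 arrays with nitrate in Cy5 the log2 ratios correlated with the fitted fold changes at r = 0.75 to 0.90 over probes, and on the 5 with nitrate in Cy3 at r = -0.92 to -0.75, while arrays with 1 condition gave r = -0.20 to 0.08. These arrays also entered the fit, and probes are not independent replicates.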

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

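Each group of 4 cultures was searched for a culture far from the other 3, over the 4 printed loci and the 7 long runs. Of these 22 groups, 4 had such a culture, where chance gives about 1 in 20. In the run from 2693 to 2704, nitrate culture D lay at 3.29, above the others at 0.93 to 1.31. In the run from 661 to 672, citrate culture 2 lay at -0.80, below the others at -0.40 to -0.36, and nitrate culture C at 0.82, above the others at 0.34 to 0.42. For lp_3441, nitrate culture C lay at 2.89, below the others at 3.27 to 3.33. Both of the groups in the run from 661 to 672 kept their sides, since all 4 nitrate cultures were above all 4 citrate cultures.

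Some probes of the array carry no locus tag and entered no comparison, yet gave signal. Spots were non-empty in 56.8% of cases for the probes named mtf_gen, 51.8% for mtf_9, 31.4% for mtf_9rev and 22.8% for SRP, against 0.041% of the negative control spots. What these names stand for is not given in the sources used here.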

How the results depend on the processing

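The counts of higher and of lower loci stayed within 1.5 times the main value in 25 and 24 of 30 alternatives, the number of loci in runs in 27 of 30, and the number of shifted windows in 24 of 25. Without each culture in turn, the counts were 231 to 288 higher, 123 to 161 lower and 148 to 194 loci in runs. Keeping only probes whose unrejected spots were all non-empty in both conditions left 185 loci to test, with 8 higher, 12 lower and 0 in runs. This filter removes loci that are often marked empty in 1 condition, so its counts say nothing on such loci. Testing each of 5873 probes gave 597 higher and 343 lower probes. The model over arrays with 1 coefficient per culture, whose error is between arrays only, gave 941 higher, 1015 lower and 1030 loci in runs, and the model that took the 16 arrays as independent gave 568, 488 and 391. A 2-fold minimum left 160 and 73. With an estimated correlation 0 windows passed, against 8. On arrays with 1 condition and with both conditions, the mean SD of log2 ratios was 0.59 and 1.00 in the main fit. It was 0.49 and 0.80 without background correction, and 0.70 and 1.18 in the authors' values. With only probes whose unrejected spots were all non-empty it was 0.70 and 0.89. On the arrays with both conditions, scaling between arrays gave 0.94 and no filter 0.87. The cause of these shifts in SD was not tested. Log2 fold changes of the 4 printed loci passed the threshold in their direction in all 27 alternatives that held them. No median of a long run changed direction, but without background correction 6 of the 7 moved by more than the spread between cultures, from 4.12 to 2.94 (2693 to 2704), -3.89 to -2.73 (2719 to 2729), -3.24 to -2.87 (1101 to 1115), 1.74 to 1.21 (2410 to 2447), 1.21 to 0.73 (635 to 656) and 0.90 to 0.58 (661 to 672). Signals close to the background can limit the size of the largest fold changes. lp_3442 ranged from 5.59 without background correction to 8.38 in the authors' values, whose scaling is unknown. What sets the upper end was not tested. No paired analysis was possible because the citrate cultures are numbered and the nitrate cultures lettered, so the labels give them no shared replicate number. The culture sets 1, 3, B, D and 2, 4, A, C as a block gave 354 higher and 273 lower loci, among them all 471 of the main calls; the sets were found in the same levels, so these counts are not independent of that choice. The image software's own log ratio and the gene lists were not run, since the former is in no column used here and the latter need gene names. This block, keeping rejected spots, a dye term per slide column and leaving out cultures 1 and D together were chosen after seeing the data, and the last 3 gave 287, 290 and 263 higher and 185, 181 and 121 lower loci. A single called locus turned its sign, without a dye term and without cultures 1 and D, and passed the threshold in neither (log2 fold change 0.786 in the main fit, -0.00502 and -0.121 in these).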

Other observations

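The test of whether citrate culture 1 was mislabelled and the fits with a dye term per slide column and a block for culture sets were chosen after the levels had been seen, and the column test below was decided on the set difference alone after both of its correlations were seen. Cultures of 1 condition also differed from each other in regions. In the run from 497 to 501, citrate cultures 1 and 4 lay at 1.70 and 1.55 and cultures 2 and 3 at 0.45 and 0.44, all above the nitrate cultures at -1.52 to -0.45. Nitrate cultures A and B lay at 1.67 and 1.46 and cultures C and D at 0.59 and 0.13 in the run from 691 to 694, above the citrate cultures at -1.17 to -0.65.

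The difference between nitrate and citrate cultures was set against all 35 splits of the 8 cultures into 4 and 4. The real split gave 471 changed loci, the highest of the other splits gave 0, and 1 of the 35 splits, the real one, gave as many. In every other split the difference between conditions falls into the spread within groups, which lowers its count. The split of 1, 3, B and D from 2, 4, A and C, described below, also gave 0. The 0 is thus no estimate of the calls that differences between cultures alone would give. Chance can be excluded at this level only if the 8 cultures are exchangeable. The culture sets described below go against that. Of the 18 splits with 2 cultures of each set on each side, the real one alone gave as many (share 0.0556, highest of the others 0), and 18 splits cannot give a share under 0.05.

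Citrate culture 1 approached the level of the nitrate cultures over the 15 loci from 1670 to 1686, at a median of 0.83 of the way from the other citrate cultures to the nitrate cultures, with 0.71 to 1.00 for the single loci. A mislabelled culture, or RNA of a nitrate culture mixed into it, would move its other changed loci alike. But over the 234 other loci changed by over 2-fold in the fit without culture 1 the median was 0.0705 of the way (95% bootstrap interval 0.05 to 0.13, with loci taken as independent). Of them, 28 lay over 0.5 of the way. Culture 1 also lay between the conditions at locus numbers 2719 to 2722, at -0.25 to 0.01. The other citrate cultures lay at 1.99 to 2.99 there and the nitrate cultures at -2.14 to -1.32. At 2727 to 2729 culture 1 lay at 1.29 to 1.87. A faulty array or dye also goes against the values, since each of its 4 arrays, 2 in each dye, placed culture 1 above the highest other citrate culture, by at least 2.02 on the log2 scale. A difference in the state of culture 1 at harvest may remain, as a hypothesis that arose from the same data and was not tested. Culture 3, at -1.18, also lay above cultures 2 and 4, at -3.28 and -3.46, in the run from 1670 to 1686. Among the citrate cultures this is the division of the sets described below. The nitrate cultures, at 1.25 (A), 1.48 (B), 1.97 (C) and 2.16 (D), were not divided by set there. The labels give no difference among the citrate cultures, and no biological explanation was tested.

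After the mean of each condition was removed, the deviations of the cultures were not independent across conditions. Over loci, cultures 1 and 3 correlated positively with B and D, and 2 and 4 with A and C (r = 0.09 to 0.38 in 8 pairs). The 8 remaining cross-condition pairs correlated negatively (r = -0.40 to -0.10). Removing the condition mean forces each culture's covariances with the cultures of the other condition to cancel, so the negative values mirror the positive ones. The split of 1, 3, B and D from 2, 4, A and C held 41.7% of the mean square of the deviations, the highest of the 18 splits that put 2 cultures of each condition on each side, where an equal share is 16.7%. On the first slide these sets coincide with the dye and the left or right column of the arrays, so a bias by column could create the pattern there. On the second slide, where column and set are crossed, the right minus left difference of the first slide correlated with the set difference at r = 0.875 over 2255 loci (0.633 to 0.892 without 1 array), which a column bias alone forbids; r with the second slide's own column difference was 0.158 (0.0041 to 0.269 without 1 array), between the bounds set beforehand and resting on single arrays, so a smaller part for the column stays open. Noise of dim probes would put the pattern into dim loci, but its mean square was 1.85 times as large in the brighter as in the dimmer loci (95% bootstrap interval over loci 1.54 to 2.23). Both bootstrap intervals given here take loci as independent. Neighbouring loci changed together, so the intervals are likely too narrow, and they leave out the spread between cultures. Cultures handled together in growth, extraction or labelling stay open and were not tested. The sets are balanced over the conditions, and a dye term per column left 290 higher and 181 lower loci, with 462 of the main calls shared.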
